A study of Mus musculus with 6 samples.

How the data were processed

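RNA was measured in RN2 mouse leukaemia cells with 1 of 3 inducible hairpins at 24 h or 48 h of doxycycline, with 3 cultures for each of the 6 groups. Per the labels' protocols, libraries were made from total RNA with a kit that keeps strand information. They were combined into 3 pools by replicate number, and each pool was run on 2 lanes of a HiSeq2000. Reads were processed with TopHat 1.4.1 and Cuffdiff against mm9, per the submitters' processing notes. The version of Cuffdiff, its normalization and whether it counted with strand are not given in the sources used here, so loci that overlap are treated as uncertain.

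The authors deposited 4 tables of 21899 genes or transcripts, 1 per Ddx5 hairpin and time. Per the file headers each holds the FPKM of the control group and of the knockdown group, the authors' test statistic, a score on which the sign gives the direction, and the authors' p-value and q-value with a test status and a significance column. Each FPKM is the authors' value for a group of 3 cultures, so the tables give no value per culture. The tables of the 2 hairpins share their control values at 48 h, and at 24 h those of all but 246 genes, which differ by at most 0.00452%. The deposited q-values equal a Benjamini-Hochberg adjustment of the deposited p-values over the genes with a completed test, and the significance column marks q-values under 0.1. Loci in the deposited tables start at 0, since 6287 loci have the gene length of the reference when counted so and 435 when not, among 19374 symbols compared. They are given here counted from 1, on mm9. The reference in hand is of another build and served for names and gene lengths.

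The read number is unknown, since FPKM values keep none, and no interval that needs counts was made. A zero can be a failed estimate in these tables, since Actb is listed at 0 in a group, so no gene is called absent.

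From the deposited values the log2 ratio of the FPKM of knockdown over control was computed for each gene, and its standard error as that ratio divided by the authors' score. No test over cultures could be made. A gene is called when it has a completed test and q under 0.05 in the authors' deposited table. Tests of 9116, 8790, 8789 and 8644 genes were completed with shDdx5.1322 and shDdx5.2086 at 24 h and then at 48 h, with median standard errors of 0.157, 0.176, 0.176 and 0.140. A failed test was recorded for 779, 812, 823 and 696 genes, and these entered no count. Differences of 2 log2 fold changes, between times or hairpins, were tested against the normal distribution with their squared errors added, and were adjusted with Benjamini-Hochberg.

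Recentring subtracts the median log2 fold change of genes with FPKM of at least 1 in both groups and recomputes the statistic, p and q. The median shift in the same order was 0.05, 0.12, -0.09 and -0.12. Relative to that shift the changes are given for lists as the median minus the median of matched random lists. Shared calls were set beside the number that independent lists would share and beside 100 simulated pairs of unchanged groups with a common control.

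The 26 gene lists (metabolic pathways, stress responses, cell cycle, ribosome, helicases and splicing, blood lineages and other cell types) were fixed before the data were examined. For each, the members called in each direction were counted, also after adjustment over the list alone, and the median was ranked among 10000 random lists of the same size drawn from 10 bins of expression. The rank is a description, since group values give no correlation between genes over cultures. Marker lists of macrophages and of neutrophil granules were added later, for a test in the closing section.

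The rule for named genes was also fixed beforehand. It takes Ddx5 and Ddx17. For each time it takes the 12 higher and 12 lower genes with the largest change in the hairpin with the smaller change, among genes called with both. These have an FPKM of at least 1 in the control or the knockdown group of both comparisons, and no small RNA is among them. It adds up to 3 genes per hairpin and direction that differ between hairpins, up to 4 called members per list, and the 5 largest differences between times per hairpin.

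The alternatives were q under 0.01, a fold change of at least 1.5, genes with FPKM of at least 1, the adjustment recomputed, recentring, small RNAs and repeated symbols left out, and pseudocounts of 1 and 0.1. A threshold of 0.1 and the removal of overlapping loci were added after the data were seen. The methods were tested on simulated data. Of genes changed 1.5-fold in the simulation, 56%, 54%, 51% and 74% were recovered (shDdx5.1322 and shDdx5.2086 at 24 h, then at 48 h), and of those changed 2-fold 98%, 98%, 95% and 100%. False calls were 2.53%, 3.80%, 6.41% and 2.79% of all calls. The simulated noise was drawn with the same standard errors that the tests then used. A low share of false calls was thus built in, and it does not test the authors' calls. Differences between times of 2-fold were recovered in 79.5% and 79% of cases.

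Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.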

Results

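The series measured RNA in RN2 cells, a mouse acute myeloid leukaemia line on the C57BL/6 background that expresses a short hairpin RNA when doxycycline is added. Cells carried a hairpin against Ddx5 (shDdx5.1322 or shDdx5.2086) or the control hairpin shRen.713, which targets Renilla luciferase, a gene that mouse cells lack. Ddx5 encodes an RNA helicase of the DEAD-box family. RNA was taken after 24 h or 48 h in 1 µg/mL doxycycline from 3 cultures per hairpin and time, which gives 6 groups and 18 libraries. Total RNA was sequenced with strand information, and the hairpin's fluorescent reporter was on in 70 to 80% of the cells, per the labels. The values used here are the authors' group FPKM, 1 value per gene and group, with their test of each Ddx5 hairpin against the control at the same time. No value per culture and no read number was in the tables analysed here, so depth is unknown and no spread between cultures can be shown. Changes are given as log2 fold changes of knockdown over control, and errors are the standard errors implied by the authors' test statistic. The libraries of a group carried a barcode of their own, so barcode and group cannot be told apart.

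The target of the hairpins was lower in all 4 comparisons. Ddx5, at 106641670 to 106649808 on chromosome 11 of mm9, went from an FPKM of 143 in the control to 49.7 with shDdx5.1322 and 37.1 with shDdx5.2086 at 24 h in the authors' deposited table. At 48 h the control had 171, against 44.3 and 43.3, in the authors' deposited table. The log2 fold change was -1.53 ± 0.30 (SE) with shDdx5.1322 and -1.95 ± 0.32 with shDdx5.2086 at 24 h, and -1.95 ± 0.27 and -1.98 ± 0.23 at 48 h. The amount left was 34.7% and 25.9% at 24 h and 26.0% and 25.4% at 48 h. The microRNA gene Mir3064 lies within the Ddx5 locus. Ddx17, the closest relative of Ddx5, had the test status of a failed test in all 4 comparisons, so its difference could not be tested. In the authors' deposited table its FPKM was 64.4 in the control and 116 and 126 with the hairpins at 24 h, and 83.7 against 120 and 116 at 48 h. The Ddx17 locus overlaps that of Kdelr3, which leaves these values uncertain.

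The comparison at 24 h asks which transcripts change early after Ddx5 is depleted. The largest shared decreases were those of Cth, Cox6a2 and Trib3, and the 12 largest included 5 members of the fixed list for the integrated stress response, the programme that the transcription factor ATF4 drives when amino acids are short or protein folding is disturbed. Cth, which makes cysteine from cystathionine (chromosome 3, 157557212 to 157588027), had a log2 fold change of -2.58 ± 0.20 with shDdx5.1322 and -2.80 ± 0.23 with shDdx5.2086. Its FPKM fell from 7.18 in the control to 1.20 and 1.03 in the authors' deposited table. Trib3, a pseudokinase induced by ATF4 (chromosome 2, 152163161 to 152169796), fell with log2 fold changes of -2.22 ± 0.23 and -2.13 ± 0.26. The neutral amino acid transporter gene Slc1a4 had -1.77 ± 0.21 and -1.75 ± 0.23, and the stress-induced gene Nupr1 had -1.74 ± 0.32 and -1.43 ± 0.35.

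Smaller decreases at 24 h were found for Chac1, whose product degrades glutathione (-1.12 ± 0.19 and -0.91 ± 0.20 with shDdx5.1322 and shDdx5.2086), and for Gpt2, an alanine aminotransferase (-1.10 ± 0.15 and -1.07 ± 0.17). Stc2, which encodes a secreted glycoprotein, had -1.08 ± 0.17 and -1.13 ± 0.19. Asns, the asparagine synthetase, had -0.92 ± 0.20 and -0.90 ± 0.22, and Mthfr, an enzyme of folate metabolism, had -0.96 ± 0.09 and -0.88 ± 0.12. The respiratory chain gene Cox6a2 had -2.50 ± 0.29 and -2.30 ± 0.32, and its locus overlaps that of Itgad. Sytl1, with a product that binds Rab proteins, had -0.98 ± 0.21 and -0.79 ± 0.23. With Ddx5, these were the 12 genes with the largest shared decrease, and all 12 stayed called with both hairpins once the fold changes were recentred on the median gene.

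Among the genes that rose at 24 h, Erp27, a protein of the endoplasmic reticulum, had the largest shared change, at 1.59 ± 0.30 and 1.89 ± 0.31. By the authors' deposited values its FPKM was low, at 0.691 in the control and 2.08 and 2.56 with the hairpins. Pcyox1l rose by 1.14 ± 0.15 and 1.24 ± 0.17, and the serpin gene Serpinb9g by 1.14 ± 0.19 and 1.21 ± 0.21. Mgl2, a macrophage lectin, had 0.89 ± 0.17 and 0.86 ± 0.19, and Siglece, a receptor for sialic acids, had 0.85 ± 0.22 and 0.99 ± 0.23. Fam120c, with an FPKM of 0.935 in the control, Lrrc51, Lipn and Ribc1 rose by between 0.89 and 1.09. For 3 further genes the locus overlaps that of another gene or copy, which leaves their values uncertain. These were Dynlt1e with Dynlt1c (2.53-fold and 2.82-fold), Rps16 with LOC100302567 (1.18 ± 0.16 and 1.32 ± 0.17) and 4930481A15Rik with Drap1 (0.83 ± 0.21 and 0.95 ± 0.23). All 12 stayed called with both hairpins after recentring.

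**Figure D1:**
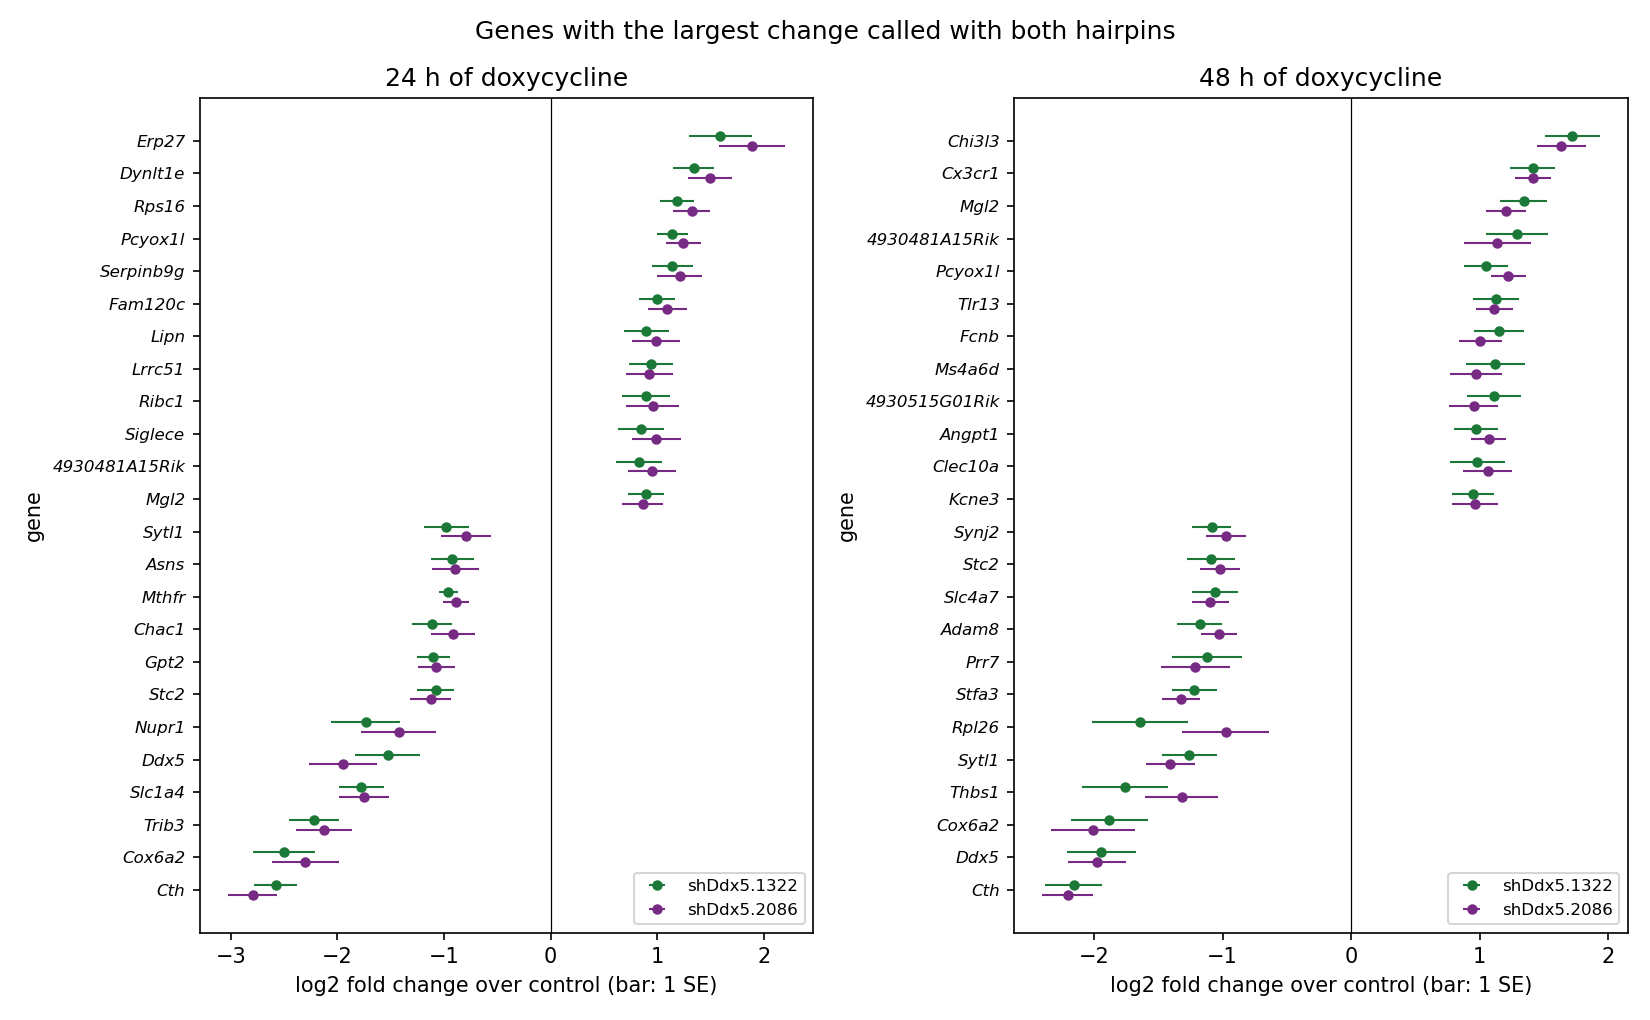
Log2 fold change over the control hairpin of the 12 genes with the largest increase and the 12 with the largest decrease among those called with both hairpins, at 24 h (left) and 48 h (right); points are the authors' group values, and bars are 1 SE. Cth lies at -2.58 and -2.80 at 24 h and remains among the largest decreases at 48 h, while Chi3l3 and Cx3cr1 lead the increases at 48 h.

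At 24 h, 290 of 9116 tested genes were called with shDdx5.1322 (200 higher, 90 lower) and 186 of 8790 with shDdx5.2086 (157 higher, 29 lower), where called means q under 0.05 in the authors' deposited table. Of these calls 69.0% and 84.4% were higher. The median gene was shifted by 0.05 and 0.12 on the log2 scale. After recentring on that median, 260 genes (129 higher, 131 lower) and 134 genes (67 higher, 67 lower) were called, of which 219 and 96 had been called before. No surplus of higher calls was left, at 49.6% and 50%. Only 15 and 16 of the calls reached a 2-fold change.

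Of the gene lists fixed before the data were examined, the one for the integrated stress and unfolded protein response stood lowest at 24 h. With shDdx5.1322, 8 of 35 tested members fell, and with shDdx5.2086, 5 of 34, while none rose. Adjusted over the list alone, 13 and 10 members were lower and 0 and 1 higher, and after recentring 10 and 7 were lower. The 5 members lower with both hairpins were Trib3, Asns, Chac1, Nupr1 and Stc2. The list's median lay 0.33 below that of random lists matched on expression with either hairpin (-0.33 and -0.33), below all 10000 of them. Such ranks compare genes and not cultures, and take no account of genes that move together, so they are no test of significance.

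Genes of the protein synthesis machinery showed a small common shift at 24 h with few calls. The median of the ribosomal protein genes lay at -0.18 and -0.17 relative to matched lists, with 71 of 74 and 70 of 75 members below the table's median. The calls were 1 and 2 higher and 0 lower (adjusted over the list alone, 1 and 2 higher and 0 lower). They were Rps16 with both hairpins and Rpl34 with shDdx5.2086, whose locus overlaps its processed copy Rpl34-ps1. Ribosome biogenesis genes lay at -0.12 and -0.15, and 1 of 46 members fell with either hairpin, which was Rrp1b in both cases (-0.41 ± 0.07 and -0.34 ± 0.08; adjusted over the list alone, 1 and 1 lower). Cholesterol biosynthesis genes lay at -0.15 and -0.13. The sole call there was Pcsk9, a regulator of the LDL receptor, at -0.55 ± 0.16 with shDdx5.1322 (of 26 tested with either hairpin, 1 and 0 lower, and 3 and 0 lower adjusted over the list alone).

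Replication-dependent histone genes lay at -0.21 with shDdx5.1322 and -0.07 with shDdx5.2086 at 24 h. In this family of near-identical copies, 1 of 63 members was called, Hist1h2ao, at -0.57 ± 0.12 and -0.86 ± 0.13 (adjusted over the list alone, 1 and 1 lower). Mitosis genes lay at 0.14 and 0.10 above matched lists and DNA replication genes at 0.09 and 0.05, with no member called among 35 and 36 and among 42 and 42, and none adjusted over the list alone (after recentring, 0 and 1 lower in the former). The MLL-AF9 and self-renewal list, genes kept on by the fusion protein in this kind of leukaemia, lay at 0.17 with either hairpin. Of its 26 genes 14 and 13 were tested, and Runx1 was called at 0.38 ± 0.07 with shDdx5.1322 (1 and 0 higher, also adjusted over the list alone). That call rests on an error well under the median of 0.157. The test of Runx1 failed with shDdx5.2086, where its log2 fold change was 0.43.

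The comparison at 48 h asks how the response develops after a further day. The largest increases included genes known from monocytes and macrophages, among them Chi3l3, Cx3cr1 and Mgl2. Chi3l3, a secreted chitinase-like protein of macrophages (chromosome 3, 105950472 to 105970482), rose by 1.72 ± 0.21 with shDdx5.1322 and 1.64 ± 0.19 with shDdx5.2086, from an FPKM of 2.18 in the control to 7.18 and 6.78 in the authors' deposited table. The chemokine receptor gene Cx3cr1 had 1.41 ± 0.17 and 1.42 ± 0.14, and the lectin genes Mgl2 and Clec10a had 1.34 ± 0.18 and 1.20 ± 0.16, and 0.98 ± 0.21 and 1.06 ± 0.19. The receptor gene Tlr13 rose by 1.13 ± 0.18 and 1.11 ± 0.15, the ficolin gene Fcnb by 1.15 ± 0.19 and 1.00 ± 0.17, and Ms4a6d by 1.12 ± 0.23 and 0.97 ± 0.20. Angpt1, which encodes the ligand of the Tie2 receptor, had 0.97 ± 0.17 and 1.07 ± 0.14. Pcyox1l, 4930481A15Rik, 4930515G01Rik and the potassium channel subunit gene Kcne3 completed the 12, with values between 0.95 and 1.29, and all 12 stayed called with both hairpins after recentring.

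The decreases at 48 h were again led by Cth (-2.16 ± 0.22 and -2.21 ± 0.20) and Cox6a2 (-1.88 ± 0.30 and -2.01 ± 0.33), next to Ddx5 itself. Thbs1, which encodes the matrix protein thrombospondin, had -1.76 ± 0.34 and -1.32 ± 0.28, from an FPKM of 187 in the control to 55.1 and 74.8 in the authors' deposited table. Stfa3, a stefin of myeloid cells, had -1.22 ± 0.18 and -1.32 ± 0.15, and the metalloprotease gene Adam8 had -1.18 ± 0.18 and -1.02 ± 0.14. Sytl1 had -1.26 ± 0.21 and -1.41 ± 0.19. Slc4a7, a bicarbonate transporter gene, had -1.06 ± 0.18 and -1.10 ± 0.14, and Stc2 had -1.09 ± 0.19 and -1.02 ± 0.16. Prr7 had -1.12 ± 0.27 and -1.21 ± 0.27, and Synj2, whose locus overlaps Serac1, had -1.08 ± 0.15 and -0.97 ± 0.16. Rpl26, whose locus overlaps Gm15772, had -1.64 ± 0.37 and -0.98 ± 0.34, and of the 12 it was the one no longer called after recentring, with shDdx5.2086.

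At 48 h, 433 of 8789 tested genes were called with shDdx5.1322 (140 higher, 293 lower) and 818 of 8644 with shDdx5.2086 (170 higher, 648 lower). The median gene was shifted by -0.09 and -0.12, and 32.3% and 20.8% of the calls were higher. After recentring, 395 genes (226 higher, 169 lower) and 531 genes (329 higher, 202 lower) were called, of which 309 and 372 had been called before. The excess of lower calls at 48 h turned into an excess of higher calls, 57.2% and 62.0%, so directions at small changes depend on the scale. Of the calls, 36 and 23 reached a 2-fold change.

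Glycolysis genes were low at 48 h, with a median of -0.37 and -0.30 relative to matched lists, below all 10000 of them. They stood lowest of the fixed lists with shDdx5.1322, and next to the ribosomal protein genes at -0.31 with shDdx5.2086. Of 20 tested members 5 fell with shDdx5.1322 and 8 with shDdx5.2086, and none rose (adjusted over the list alone, 8 and 9 lower). After recentring 2 and 3 were called. The lactate transporter gene Slc16a1 had -0.76 ± 0.18 and -0.67 ± 0.14, and Pdk1, a kinase that inhibits pyruvate dehydrogenase, had -0.73 ± 0.18 and -0.71 ± 0.14. The glucose transporter gene Slc2a1 (-0.61 ± 0.17 and -0.56 ± 0.14) and Pfkl (-0.58 ± 0.19 and -0.50 ± 0.15) fell with both hairpins too, but after recentring Slc2a1 was called with shDdx5.2086 alone and Pfkl with neither. At 24 h the list lay at -0.11 and -0.09, with Pdk1 as the sole call (-0.54 ± 0.16 with shDdx5.1322; of 21 tested with either hairpin, 1 and 0 lower, also adjusted over the list alone).

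The integrated stress and unfolded protein response list remained low at 48 h, at -0.20 and -0.17, below all matched lists. Of 34 tested members 4 fell with shDdx5.1322 and 12 with shDdx5.2086 (adjusted over the list alone, 11 and 17), and 4 and 4 after recentring. The 4 members lower with both hairpins were Stc2, the stress-induced gene Ddit4 (-0.93 ± 0.22 and -0.78 ± 0.19), the amino acid transporter gene Slc7a5 (-0.77 ± 0.18 and -0.64 ± 0.14) and Aldh18a1, an enzyme of proline synthesis (-0.67 ± 0.12 and -0.64 ± 0.10).

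Ribosomal protein genes lay at -0.28 and -0.31 at 48 h, and all 75 tested members were below the table's median with either hairpin. Of them 2 and 4 fell (adjusted over the list alone, 2 and 1; after recentring, 2 and 1). Rps16 and Rpl26, both with overlapping loci, were lower with both hairpins. Ribosome biogenesis genes lay at -0.19 and -0.16 with 3 and 4 of 46 members lower (adjusted over the list alone, 3 and 5; after recentring, 1 and 1). Rrp1b had -0.73 ± 0.07 and -0.56 ± 0.07, and Mybbp1a had -0.59 ± 0.18 and -0.48 ± 0.14 but was called with neither hairpin after recentring. Cholesterol biosynthesis genes lay at -0.16 and -0.15, and of 26 members 4 and 7 fell (adjusted over the list alone, 5 and 11; after recentring, 2 and 2). Pcsk9 was lower with both hairpins (-0.79 ± 0.20 and -0.73 ± 0.17), as were Hmgcs1 (-0.48 ± 0.13 and -0.41 ± 0.10), Mvd and Nsdhl, which each lost the call with a hairpin or both after recentring.

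Of the fixed myeloid differentiation list, 3 of 31 members rose with shDdx5.1322, and 4 of 32 rose and 3 fell with shDdx5.2086 (adjusted over the list alone, 5 higher, and 6 higher and 4 lower; after recentring, 5 and 6 higher and none lower). Fcnb, the growth factor receptor gene Csf1r (0.80 ± 0.19 and 0.79 ± 0.14) and the glucan receptor gene Clec7a (0.93 ± 0.18 and 0.84 ± 0.15) rose with both hairpins. The list's median lay at 0.06 and 0.07 relative to matched lists, at percentiles 92.7 and 98.0. At 24 h it lay at -0.04 and 0.09, at percentiles 13.2 and 99.4, so the hairpins did not agree. Then 0 and 2 of 31 members rose (adjusted over the list alone, 0 and 5). These were Fcnb and Cd68 with shDdx5.2086, which were not called after recentring.

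DNA replication genes lay at 0.22 and 0.18 above matched lists at 48 h and mitosis genes at 0.17 and 0.08. In the former, 1 and 2 of 42 members rose (adjusted over the list alone, 1 and 1; after recentring, 2 and 2), among them E2f2, a transcription factor of the G1 to S transition, at 0.69 ± 0.17 and 0.56 ± 0.14. In the latter 0 and 1 of 35 and 36 were called, Cdc25b at -0.27 ± 0.06 with shDdx5.2086 (adjusted over the list alone, 0 and 1 lower), a call lost after recentring. The test of Cdc25b with shDdx5.1322 failed. Histone genes lay at 0.12 and 0.06, on the other side from 24 h, with 0 and 1 of 62 lower and none adjusted over the list alone. The called member, Hist2h3c2-ps, was lost after recentring. The MLL-AF9 list lay at 0.14 and 0.15 with no member called among 13, and none adjusted over the list alone. It holds 26 genes, of which 20 met the FPKM minimum of 1. Those without a completed test cannot be read as unchanged.

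**Figure D2:**
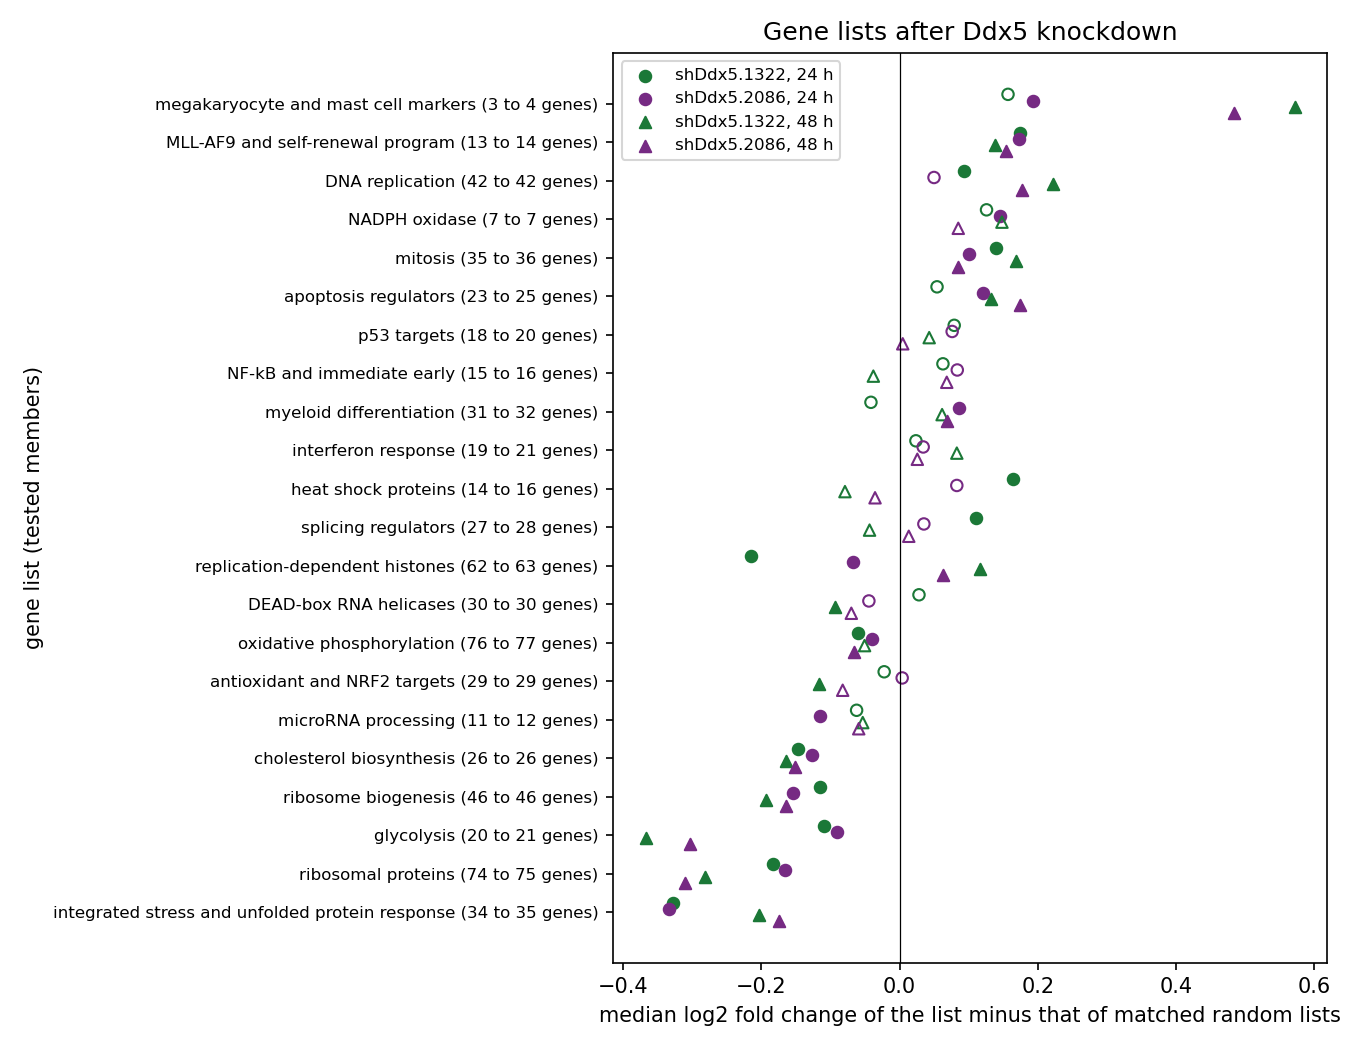
Median log2 fold change of each fixed gene list minus the median of 10000 random lists of the same size matched on expression, for both hairpins (colours) at 24 h (circles) and 48 h (triangles); filled symbols lie below the lowest or above the highest 2.5% of the random lists. The integrated stress and unfolded protein response list lies at -0.33 with both hairpins at 24 h, and glycolysis at -0.37 and -0.30 at 48 h.

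Setting the 2 hairpins side by side asks which changes do not come from a side effect of a single hairpin. At 24 h, 131 genes were called in the same direction with both (104 higher, 27 lower) and none in opposite directions. A further 134 and 51 genes tested in both were called with shDdx5.1322 or shDdx5.2086 alone. Independent lists would share 3.13 higher and 0.278 lower genes of 8765. At 48 h, 379 genes were shared (107 higher, 272 lower) and none opposite, with 31 and 410 called with a single hairpin, against 2.20 and 21.6 shared by independent lists among 8516 genes. Of these single calls, 132 of 134 and 50 of 51 at 24 h had the same sign with the other hairpin. At 48 h 30 of 31 and 409 of 410 did. The common control and the shift of the median gene also favour equal signs. In 100 simulated pairs of unchanged groups with a common control at most 0 genes were shared, but such groups yield hardly any calls, so this does not show how far the common control adds to the overlap of real calls. After recentring 112 (52 higher, 60 lower) and 303 (175 higher, 128 lower) were shared. Across genes, which are not independent replicates, the fold changes of the hairpins had a covariance of 0.0404 at 24 h and 0.0564 at 48 h. Simulated unchanged groups with a common control and the nominal errors gave 0.0199 and 0.0136. The correlations were 0.895 and 0.922, with 0.448 and 0.365 in that simulation. The spread of the hairpin difference was only 0.298 and 0.269 of its nominal error at 24 h and 48 h. It put the variance of a knockdown group at 0.00268 and 0.00195. The simulated values therefore rest on errors larger than that spread and do not measure the control's part. The control of a time could not be split, so part of the overlap may rest on it.

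**Figure D3:**
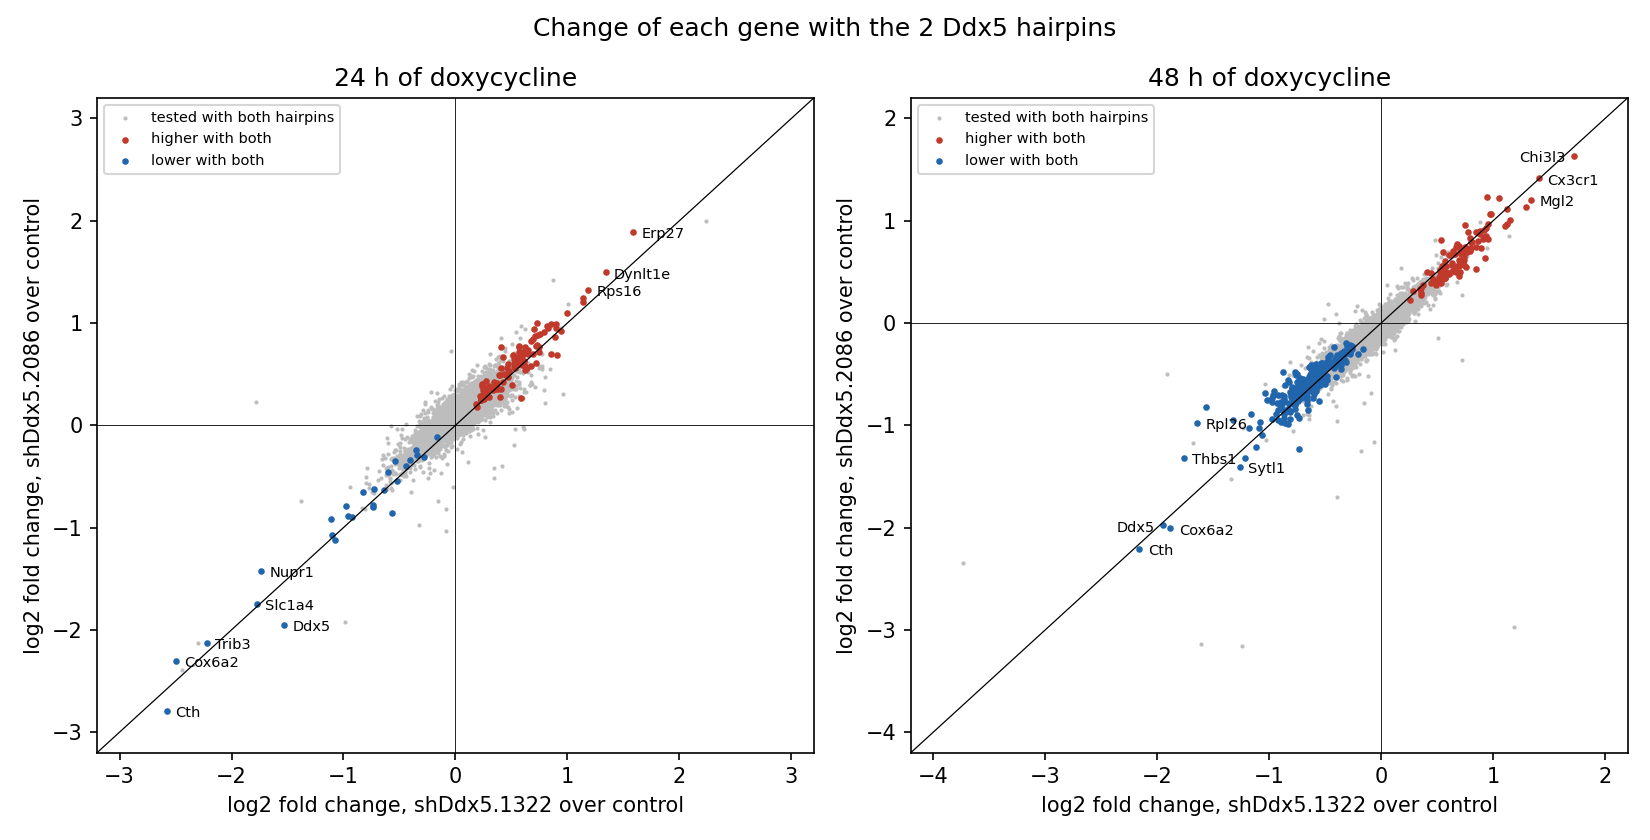
Log2 fold change of each tested gene with shDdx5.1322 (x axis) and shDdx5.2086 (y axis) over the shared control at 24 h (left) and 48 h (right); coloured points are genes called in the same direction with both hairpins, and the line marks equal change. The 131 shared calls at 24 h and the 379 at 48 h lie along the line.

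At both times and with both hairpins, 46 genes were called in the same direction (29 higher, 17 lower), and 38 of these remained after recentring. The rule for named genes had singled out Cth, Cox6a2, Stc2, Sytl1, Rrp1b, Mgl2, Pcyox1l, 4930481A15Rik and Ddx5 at both times. Further members, chosen for mention after their values were seen, were the urea cycle enzyme gene Ass1 and the folate carrier gene Slc19a1 on the lower side, and the cell cycle inhibitor gene Cdkn2c and the transcription factor gene Gfi1b on the higher side. Rps16 was the 1 gene called with both hairpins at both times in opposite directions, higher at 24 h and lower at 48 h. By the authors' deposited values its FPKM moved most in the control, from 59.5 at 24 h to 210 at 48 h. With shDdx5.1322 it went from 135 to 102, and with shDdx5.2086 from 149 to 130.

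The difference between the effect at 48 h and at 24 h was tested gene by gene. With shDdx5.1322, 56 of 8700 genes differed (4 more positive, 52 more negative at 48 h), and with shDdx5.2086, 50 of 8463 (2 and 48). After recentring, 33 (16 and 17) and 8 (5 and 3) differed, 21 and 5 of them in common with the values before. Rps16 had the largest difference with shDdx5.1322 (-2.22 ± 0.25), followed by the protease inhibitor gene Spint2 (-1.48 ± 0.33), the tetraspanin gene Cd9 (-1.27 ± 0.23), Gm5803 (-1.25 ± 0.24) and the transcription factor gene Bhlhe40 (-1.21 ± 0.28). Such differences include any change of the control between the times. The authors' deposited FPKM of Bhlhe40 went from 1.47 to 3.32 in the control and from 1.82 to 1.78 with shDdx5.1322. For Spint2, Cd9 and Gm5803 the control rose and the knockdown fell. With shDdx5.2086, Rpl34 (-4.64 ± 0.27) and its copy Rpl34-ps1 (2.97 ± 0.33) came before Rps16 (-2.01 ± 0.23), Stfa3 (-1.16 ± 0.22) and Mrpl12 (-1.03 ± 0.22), and Mrpl12 was not called after recentring.

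After recentring, the genes with a higher effect at 48 h included Ms4a6c with both hairpins (0.82 ± 0.13 and 0.61 ± 0.13). With shDdx5.1322 they also included the microglial and macrophage receptor gene Trem2 (1.08 ± 0.28), Pld4 (1.07 ± 0.23) and Cx3cr1 (0.88 ± 0.23). These 4 were chosen for mention after their values were seen.

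Few genes were called as different between the hairpins, by a conservative test. At 24 h 2 of 8760 genes differed, Iqsec1 by 0.17 ± 0.03 and Syvn1 by 0.27 ± 0.05, both more positive with shDdx5.2086, and 0 after recentring. At 48 h 0 of 8514 genes differed by the normal test of the difference, and 5 did at an unadjusted p under 0.05 (26 at 24 h). The errors were added as if independent although the control is shared. With part of the control's share of the variance taken out, 3 genes differed at 24 h and 0 at 48 h. The spread of the hairpin difference over genes was 0.298 and 0.269 of its nominal error at 24 h and 48 h, so the test had little power for small differences.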

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

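The tests of overall scale and of low-expressed genes below were chosen after the result was seen, and that of RNA content was stated before. Differences between times were planned, and the look at genes with a failed test was not.

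Named genes whose effect differed between 48 h and 24 h with shDdx5.1322, as log2 fold change at 48 h minus that at 24 h, were Rps16 (-2.22), Spint2 (-1.48), Cd9 (-1.27), Gm5803 (-1.25), Bhlhe40 (-1.21), Stfa3 (-1.03), Txn2 (-1.02), Mrpl12 (-0.99), Rrs1 (-0.95), Hnrnpa2b1 (-0.73) and Iqsec1 (-0.17). With shDdx5.2086 they were Rpl34 (-4.64), Rpl34-ps1 (2.97), Rps16 (-2.01), Stfa3 (-1.16), Mrpl12 (-1.03), Bhlhe40 (-1.0), Adam8 (-0.99), Txn2 (-0.98), Cd9 (-0.94), Iqsec1 (-0.44), Hnrnpa2b1 (-0.38) and Syvn1 (-0.33). Between the hairpins at 24 h, Iqsec1 (0.17) and Syvn1 (0.27) differed. After recentring, Mrpl12, Rrs1 and Iqsec1 no longer differed with shDdx5.1322, and of those named with shDdx5.2086 only Rpl34, Rpl34-ps1, Rps16 and Stfa3 still did. Between the hairpins, neither Iqsec1 nor Syvn1 differed any more. Iqsec1 and Syvn1 owe their calls to standard errors of 0.03 and 0.05 on the difference, far under the median of 0.236. Calls of other small changes also rest on small errors. These were 0.024 for Psrc1 and 0.075 for Runx1 with shDdx5.1322 at 24 h (median 0.157). With shDdx5.2086 they were 0.052 for Bcl2l11 at 24 h (median 0.176) and 0.062 for Cdc25b at 48 h (median 0.140).

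Rpl34 and Rpl34-ps1 exchanged their values in the table of shDdx5.2086 at 24 h. In the authors' deposited table, Rpl34 went from 44.2 to 745 FPKM and Rpl34-ps1 from 814 to 75.8. Their sum was 858 in the control and 821 with the hairpin, a log2 ratio of -0.06. The values of the overlapping copies are therefore uncertain taken singly.

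Several genes moved alike with both hairpins but had a failed test in both tables, among 701 such genes at 24 h and 637 at 48 h. No test covers them, and their values are the mean log2 fold change of both hairpins. Those listed had an FPKM of at least 1 in each group and at least a 1.5-fold change with each hairpin after recentring. At 24 h these were Ddx17 (0.91), whose locus overlaps Kdelr3, Txnip (1.27), which encodes an inhibitor of glucose uptake, and Vegfa (-0.55). At 48 h they were Txnip (0.85), the progenitor marker gene Cd34 (0.58), the transcription factor genes Mef2c (0.53), Meis1 (0.55) and Tcf19 (0.58), and D330041H03Rik (0.93). Lower at 48 h were Eif4a2 (-0.82), H2-T22 (-0.81), Mrps10 (-0.80), Prepl (-0.87) and Snord2 (-1.31). Except for Txnip, these genes fell short of that rule at the other time. With shDdx5.1322 and shDdx5.2086 the values were -0.76 and -0.63 for Vegfa and 0.52 and 0.46 for Ddx17 at 48 h. At 24 h they were 0.65 and 0.52 for D330041H03Rik, 0.49 and 0.56 for Tcf19, 0.49 and 0.49 for Meis1, 0.32 and 0.35 for Mef2c, and 0.21 and 0.37 for Cd34. They were -0.28 and -0.34 for Eif4a2, -0.41 and -0.36 for H2-T22, -0.25 and -0.20 for Mrps10, 0.11 and -0.03 for Prepl and 1.43 and 0.01 for Snord2, so the last 2 did not fall at 24 h.

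Calls were mostly higher at 24 h and mostly lower at 48 h. In all 40 expression bins of the 4 tables the median had the sign of the overall shift, so a difference in overall FPKM scale may account for the imbalance. Low-expressed genes alone are argued against, since the upper bins had at least 0.976 of the shift. Whether the RNA content of the cells changed cannot be told apart from such a scale difference, because 0 added RNA standards were in the tables.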

How the results depend on the processing

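The threshold of 0.1 and the removal of overlapping loci were chosen after seeing the data, and the others were planned. With q under 0.01 the calls were 162 (shDdx5.1322, 24 h), 250 (shDdx5.1322, 48 h) and 416 (shDdx5.2086, 48 h), the shared calls were 82 at 24 h and 205 at 48 h, and the differences between times were 36 and 32, through the stricter threshold itself. With a fold change of at least 1.5 the calls were 121 and 93 at 24 h and 266 and 228 at 48 h with shDdx5.1322 and shDdx5.2086, and the shared calls 61 and 178. Recentring gave 531 calls with shDdx5.2086 at 48 h, 33 and 8 differences between times with shDdx5.1322 and shDdx5.2086, and 0 between hairpins at 24 h, since a shift common to most genes was taken out. No called fold change of a named gene changed sign. Recentring did turn the balance of the calls, from 140 higher and 293 lower to 226 and 169 (shDdx5.1322, 48 h), from 170 and 648 to 329 and 202 (shDdx5.2086, 48 h), from 107 and 272 to 175 and 128 (shared, 48 h) and from 104 and 27 to 52 and 60 (shared, 24 h). The other settings kept each count within 1.5 times of the main one.

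For named genes, recentring took the call shared by both hairpins from 15 values, left 110 in place, and moved 8 others by more than their standard error, if they had any. Counted per hairpin, 47 of 209 named calls were lost, 3 gained and 0 turned. A pseudocount of 0.1 left 133 values in place, and 1 moved 43 of 133. Recentring cannot move a list among random lists, since it shifts all genes alike. Still, 1 of 44 list medians crossed the limit with it (MLL-AF9, 48 h, at percentiles 98.1 and 99.25 before). New random draws may have done this, which was not tested. Whether such draws account for the antioxidant list at 48 h, which crossed it with a pseudocount of 1, was not tested either. No paired analysis was possible because the tables hold no value per culture, and leaving out each replicate was not run for the same reason. A 1.5-fold change was recovered in 51% to 74% of simulated cases, so a gene without a call can still have changed by that much or less.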

Other observations

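The tests of scale, nutrient depletion, chaperones, macrophage markers, granule markers and the control's own course below were chosen after the result was seen. That of the control's own course took the place of a rule set before the result, at most 50% without any SE added, by which the course would have been excluded. The 2 SE were chosen with the shares for 0, 1 and 2 SE in view.

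Of p53 targets, as in the lists below with shDdx5.1322 and shDdx5.2086 in that order, 2 and 1 rose at 24 h, and at 48 h 0 and 2 rose and 0 and 1 fell (adjusted over the list alone, 4 and 1 higher and 1 and 0 lower at 24 h, and 0 and 2 higher and 0 and 1 lower at 48 h). Psrc1, higher with shDdx5.1322 at 24 h (0.23 ± 0.02), and Trp53inp1, higher with shDdx5.2086 at 48 h, had a failed test with the other hairpin. The growth suppressor gene Sesn1 rose with both hairpins at 24 h (0.41 ± 0.12 and 0.56 ± 0.14), though with neither after recentring, when 1 and 0 list members were higher at 24 h and 0 and 3 at 48 h and none lower. Of apoptosis regulators, the sole calls were Bcl2l11 at 24 h (0.39 ± 0.05) and Bcl2l2 at 48 h (-0.49 ± 0.15), both with shDdx5.2086 (adjusted over the list alone, 2 and 2 higher at 24 h, and 0 and 1 lower at 48 h), and Bcl2l2 was lost after recentring, which gave 1 higher and 0 lower with shDdx5.2086 at 48 h. The median of this list lay at 0.05 and 0.12 relative to matched lists at 24 h and at 0.13 and 0.17 at 48 h, the latter at percentiles 99.5 and 100, with 17 of 23 and 17 of 24 members above the table's median. Of antioxidant genes, 1 and 1 rose at 24 h, which was Txn2 (0.57 ± 0.15 and 0.72 ± 0.17), and 3 and 5 fell at 48 h (adjusted over the list alone, 1 and 1 higher, and 3 and 7 lower), with the transporter gene Abcc1 lower with both (-0.77 ± 0.19 and -0.75 ± 0.15). After recentring 1 and 1 were lower at 48 h, and Gclm and Prdx3 were called with neither hairpin. No NADPH oxidase gene of 7 and no microRNA processing gene of 12 was called, also adjusted over the list alone, and recentring gave 1 higher in the former with shDdx5.2086 at 48 h. In the interferon list Ifit2 (0.63 ± 0.17 and 0.56 ± 0.14) and Herc6 (0.56 ± 0.17 and 0.49 ± 0.14) rose with both hairpins at 48 h, while Ddx58 and Bst2 fell with both but lost the call with a hairpin or both after recentring. In that list 2 and 0 rose at 24 h, and at 48 h 4 and 2 rose and 2 and 3 fell (adjusted over the list alone, 2 and 0 higher and 2 and 0 lower, then 4 and 5 higher and 2 and 3 lower). After recentring, 4 and 6 were higher and 0 and 1 lower at 48 h, and 1 and 0 higher and 1 and 0 lower at 24 h.

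Of oxidative phosphorylation genes, Cox6a2 fell in all 4 comparisons and Ndufv3 with shDdx5.2086 at 48 h (-0.37 ± 0.11), which made 1, 1, 1 and 2 lower of 76 or 77 (the same adjusted over the list alone). The list's median lay at -0.06 and -0.04 relative to matched lists at 24 h and at -0.05 and -0.07 at 48 h, and was among the lowest 2.5% of them except with shDdx5.1322 at 48 h. Of DEAD-box helicases, Ddx5 fell throughout, with Ddx58 at 48 h and Ddx50 with shDdx5.2086 at 48 h (1, 1, 2 and 3 lower of 30, also adjusted over the list alone). Splicing regulators gave 2 and 1 higher at 24 h, with Hnrnpa2b1 at 0.58 ± 0.06 and 0.27 ± 0.07, and 0 and 1 lower at 48 h (adjusted over the list alone, 4 and 1 higher, then none). Heat shock genes gave 2 and 0 higher at 24 h and 0 and 2 lower at 48 h, and immediate early and NF-kB genes gave 0 and 1 higher and then 1 and 4 lower (adjusted over the list alone, 2 and 0 then 0 and 2 for heat shock, and 1 and 2 higher with 1 and 0 lower, then 1 and 4 lower, for immediate early genes). The 2 heat shock genes higher at 24 h, Hspa1a and Hspa1b, had no completed test with shDdx5.2086. They were 1.79-fold and 1.69-fold with it, against 1.79-fold and 1.65-fold with shDdx5.1322. After recentring Ndufv3, Ddx50, Tra2a (the lower splicing regulator), Hnrnpa2b1 with shDdx5.2086 and the heat shock genes at 48 h were not called, 1 and 0 heat shock genes were higher at 24 h, and the immediate early and NF-kB list had 0 higher and 1 and 0 lower at 24 h and 0 and 1 lower at 48 h. Further list medians were among the lowest or highest 2.5% of matched lists with a single hairpin alone. With shDdx5.1322 these were heat shock genes (0.16), splicing regulators (0.11) and DNA replication genes (0.09) at 24 h. At 48 h they were DEAD-box (-0.09) and antioxidant genes (-0.12). With shDdx5.2086 at 24 h they were NADPH oxidase (0.15), microRNA processing (-0.12), apoptosis (0.12), myeloid differentiation (0.09) and megakaryocyte and mast cell genes (0.19). Markers of other cell types were nearly unmeasured. At most 1 B cell gene, 1 T or NK cell gene, 0 erythroid genes and 1 stromal gene were tested, and no B cell or T or NK cell gene was called (adjusted over the list alone, 1 higher each with shDdx5.1322, at 48 h and at 24 h). The stromal gene Pdgfrb rose by 0.56 ± 0.10 and 0.46 ± 0.10 at 48 h and, with shDdx5.2086, by 0.57 ± 0.08 at 24 h (its test with shDdx5.1322 failed then), also adjusted over the list alone and after recentring. Of the 3 to 4 tested megakaryocyte and mast cell genes, Cpa3 rose with shDdx5.2086 (0.57 ± 0.17 at 24 h and 0.81 ± 0.14 at 48 h) and Gata2 fell with it at 48 h (-0.42 ± 0.14), calls of which that of Cpa3 at 48 h was kept after recentring, when Cpa3 was also called with shDdx5.1322 (adjusted over the list alone, 0 and 1 higher at 24 h, and 2 and 1 higher and 1 and 1 lower at 48 h).

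The amount of Ddx5 left, 25.4% to 34.7%, lies beside the 20 to 30% of cells without the reporter, per the labels. No value here tells whether that part came from those cells.

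In the integrated stress list, 5 of the 34 members tested with both hairpins were called lower with both at 24 h. Their median log2 fold change after recentring was -1.20. Genes picked by their call could hardly lie near 0, so this value does not weigh a scale difference. The whole list lay at -0.33 and -0.33 relative to matched lists at 24 h, which a shift common to all genes cannot produce. A general fall of the unfolded protein response is argued against by chaperone genes of the endoplasmic reticulum, with medians of 0.23 and 0.24 after recentring. Nutrient depletion building up in the control cultures stays open, since the 24 h control enters both the calls and the control's own change. From 24 h to 48 h the 5 genes changed in the control by a median of -0.32 relative to all genes, and by -0.0230 with 2 SE of the 24 h control added, while all 34 members, called or not, had -0.10 with 13 positive. A property of the single control hairpin line also stays open, since both hairpins were set against it.

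The largest increases at 48 h included Chi3l3, Cx3cr1 and Mgl2, known from monocytes and macrophages, and 3 of 31 members of the fixed myeloid list rose with both hairpins. Macrophage markers outside the fixed lists lay at percentiles 98.7 and 99.97 of matched random lists (61.6 and 99.88 already at 24 h), in line with a small shift toward macrophage gene expression relative to other genes, but not particular to it, since their relative medians of 0.11 and 0.14 stood beside 0.22 and 0.18 for DNA replication, 0.14 and 0.15 for MLL-AF9, 0.13 and 0.17 for apoptosis and 0.57 and 0.48 for 3 megakaryocyte and mast cell genes. Their own medians were 0.01 and 0.02, and of 23 tested 0 rose and 2 fell with shDdx5.1322, and 2 rose and 2 fell with shDdx5.2086. Granule markers of neutrophils outside the fixed lists lay at percentiles 96.2 and 81.5, with 2 and 2 of 9 and 8 tested genes higher and 0 lower, also after recentring, so a wider rise of myeloid maturation genes cannot be told apart from it. Knockdown cultures further along the control's own course cannot be told apart either, as the 48 h control enters both with opposite signs, and 26.4% of the shared calls moved as the control did, 40.9% with 1 SE of that control added toward each call and 57.3% with 2.

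The marker lists were trimmed after their values had been seen, to the 38 of 45 macrophage and 13 of 27 granule genes that stood in no fixed list. Untrimmed, the percentiles were 99.1 and 99.93 for macrophage and 99.89 and 99.95 for granule markers.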
